A study of Mus musculus with 9 samples.

How the data were processed

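RNA from sorted immature erythroid cells of mouse bone marrow was sequenced in 9 libraries, 3 in each of 3 groups. Per the labels' protocols, RNA was purified on columns with DNase digestion and turned into libraries from total RNA with a NuGEN Encore Complete kit. Per the submitters' processing notes, TopHat2 2.0.8b, Bowtie2 2.1.0 and Cuffdiff 2.1.1 were used with the mouse build mm10. The gene annotation, the filters, the scaling across libraries and the use of strand are not given in the sources used here.

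The authors deposited 1 table of gene differential expression, with 23285 genes in each of 3 comparisons. FPKM values (fragments scaled by transcript length and by the number of mapped fragments) are the authors' values, 1 per gene and group, so the 3 libraries of a group were already pooled. The log2 fold change in the authors' deposited table is the log2 of one group's FPKM over the other's, with no pseudocount. The deposited test statistic is a score for that log ratio, and the p-value and q-value beside it are the authors' as well. Recomputing showed that the deposited q is the Benjamini-Hochberg adjustment over the 31813 tested gene results of the 3 comparisons together, with a largest difference of 5.27e-07. The smallest deposited p, 5e-05, is a floor reached by 2570 of those results, and it corresponds to a q of 0.000619. For 96.0% of the tested results the p in the authors' deposited table lies below the p of the same statistic read as a standard normal. At a q between 0.045 and 0.055 the median size of the deposited statistic was 1.57, whose normal p would be 0.117.

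No value per library was used, so no SD, no n per value, no leave-one-out fit and no model across libraries could be computed here. The depth of each library is unknown for the same reason, and neither an interval nor a detection floor from counts is given. The error printed after a log2 ratio as ± is the standard error implied by the authors' deposited test statistic, that is the size of the log2 ratio divided by that of the statistic. Folds, percentages and standard errors were computed here from the deposited values.

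Genes counted as called have a q below 0.05 and a completed test in the authors' deposited table. The 3 comparisons were KOa against FFa, KOb against FFa and KOb against KOa. The tests compare the pooled libraries of each group, and the labels do not say whether the 3 libraries of a group came from separate mice, so the spread they measure may be partly technical. KOb cells were sorted as TER119-negative and the other groups as TER119-positive, so the degree of deletion and the sort gate differ together. Both mutant groups carry Mx1Cre and the control does not, so Cre and the deletion differ together as well, and the labels used here do not say whether the control mice received poly(I:C).

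Before the data were examined, the test, 30 gene lists (26 curated and 4 defined by a symbol rule), the alternatives and the rule for named genes were fixed. The lists cover the TRIM28 complex, adult and embryonic globins, heme synthesis, iron handling, the red cell membrane, erythroid transcription factors, late erythroblast maturation, stem and early progenitor genes, the EPO and STAT5 response, autophagy, the interferon response, imprinted and germline genes, p53 targets, the integrated and ER stress response, mitotic and DNA replication genes, and Zfp-named zinc finger, ribosomal protein, histone and proteasome genes. Markers of granulocytes, macrophages and monocytes, megakaryocytes, B cells, T and NK cells, mast cells with basophils and eosinophils, dendritic cells, and stromal and endothelial cells form the remaining lists. Some lists share genes, so their results are not separate. Shared genes include Hmox1 and Slc40a1 in the iron and macrophage lists, Axl in the imprinted and macrophage lists, and Trib3 in the EPO and stress lists. Late maturation genes shared with another list include Bnip3l (autophagy), Rhag (red cell membrane) and Tal1 (erythroid transcription factors). Sesn2 is in the p53 and stress lists, and Psmb8 in the interferon and proteasome lists. Named genes are Trim28, the 10 largest rises and the 10 largest falls of each comparison among called genes with an FPKM of at least 1 in the higher group and above 0 in both, and from each list up to 3 called members of largest change. Where no member passed, the 2 members of highest mean FPKM can be named. Small RNA genes and entries that join several genes are not named by this rule.

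For each list and comparison, the median deposited log2 ratio over members with an FPKM of at least 1 in one of the groups was set against 10000 random lists of the same size, drawn from the tested genes in 20 bins of mean expression. The permutation p is two-sided, over genes, and was adjusted with Benjamini-Hochberg over all lists and comparisons. Lists with fewer than 3 such members got no test. Genes of a pathway are not independent, and with group values their correlation could not be estimated, so limma 3.58.1 (cameraPR, in R 4.3.3) was run as an alternative with preset correlations of 0.01 and 0.05. No estimated correlation stands behind any list p. Members that passed were also counted with q values adjusted over the list alone.

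KOa and KOb share the control libraries. Overlap of their calls was therefore set beside the overlap of independent lists and beside 100 simulations of unchanged groups that share FFa, drawn from the spread implied by the deposited statistics. The control could not be split, since only its pooled value was used. Neighbouring genes on the chromosomes were tested with 10000 shuffles of the calls.

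Alternatives tried were a q below 0.01, adjustment within a comparison, FPKM minimums of 1 and 5, a 2-fold minimum with and without a pseudocount of 1, centring of the ratios, and cameraPR for the lists. Calls from the deposited statistic read as a standard normal, calls without genes listed at 0, calls without marker genes, and 2 trimmed lists were added after seeing the data. The trimmed lists are the TRIM28 complex list without Trim28 and the ribosomal protein list without Rps6k kinase genes and Rpl39l.

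The list test, and calls from the statistic read as a standard normal, were tested on simulated data. Calls by the deposited q, used for the counts of called genes, were not tested in this way. Unshifted random lists are set against random lists, so a share near 5% is given by construction. Of 200 random lists of 25 genes with no added shift, 5%, 4% and 6% passed an unadjusted permutation p of 0.05 in KOa against FFa (8258 genes), KOb against FFa (8420 genes) and KOb against KOa (8086 genes). With 0.5 log2 added, 97%, 96% and 99.5% passed. With the statistic read as a standard normal, 21.5% of 2-fold and 78.5% of 4-fold changes were called in KOa against FFa (8311 genes), 27% and 85% in KOb against FFa (8478 genes), and 31.5% and 92% in KOb against KOa (8137 genes). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The build of the coordinates is mm10, and positions are counted from 1.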

Results

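Gene expression was measured by RNA sequencing of immature erythroid cells from mouse bone marrow, in which the floxed gene Trim28 had been deleted in 2 of the 3 groups. TRIM28 is a transcriptional corepressor that KRAB zinc finger proteins bring to chromatin. FFa, the control, consisted of CD71hi TER119-positive cells from floxed mice without Cre. KOa cells came from floxed mice with Mx1Cre, whose recombinase is switched on by poly(I:C), and were sorted through the same gate. KOb cells came from such mutants too, but were CD71hi and TER119-negative. Each group held 3 libraries. The mutant mice had received 5 poly(I:C) injections and were analysed 2 weeks later, per the series description. Whether the control mice received poly(I:C) is not given in the labels used here. CD71 is the transferrin receptor of young erythroblasts, and TER119 marks erythroid cells from the proerythroblast stage onward.

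The deposited values are group FPKM values, so the depth per library is unknown and no value carries an SD, and how many libraries show a direction cannot be counted. The FPKM of all genes added up to 1239023 in FFa, 1275908 in KOa and 659009 in KOb, and beta-globin genes made up 63.9%, 75.7% and 52.5% of these sums. At least 1 FPKM was reached by 8042 genes in FFa, 7679 in KOa and 7957 in KOb. Over genes with an FPKM of at least 1 in both groups, the median log2 ratio was -0.05 in KOa against FFa, 0.01 in KOb against FFa and 0.05 in KOb against KOa.

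Trim28 (chromosome 7, 13024152 to 13031032 of mm10) had an FPKM of 26.0 in FFa, 6.64 in KOa and 4.76 in KOb. Its log2 ratio to the control fell by 1.97 ± 0.30 in KOa, to 25.6% of FFa, and fell by 2.45 ± 0.30 in KOb, to 18.3%. The series description gives residual mRNA of 26% and 18%, with 5 to 8% and 1 to 4% of the gene undeleted. Between the mutants the log2 ratio was -0.48 ± 0.32, with a q of 0.0535 in the authors' deposited table, which missed the threshold. The position of the floxed exons is not given in the sources used here, so reads from an undeleted part of the gene cannot be set apart.

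**Figure D1:**
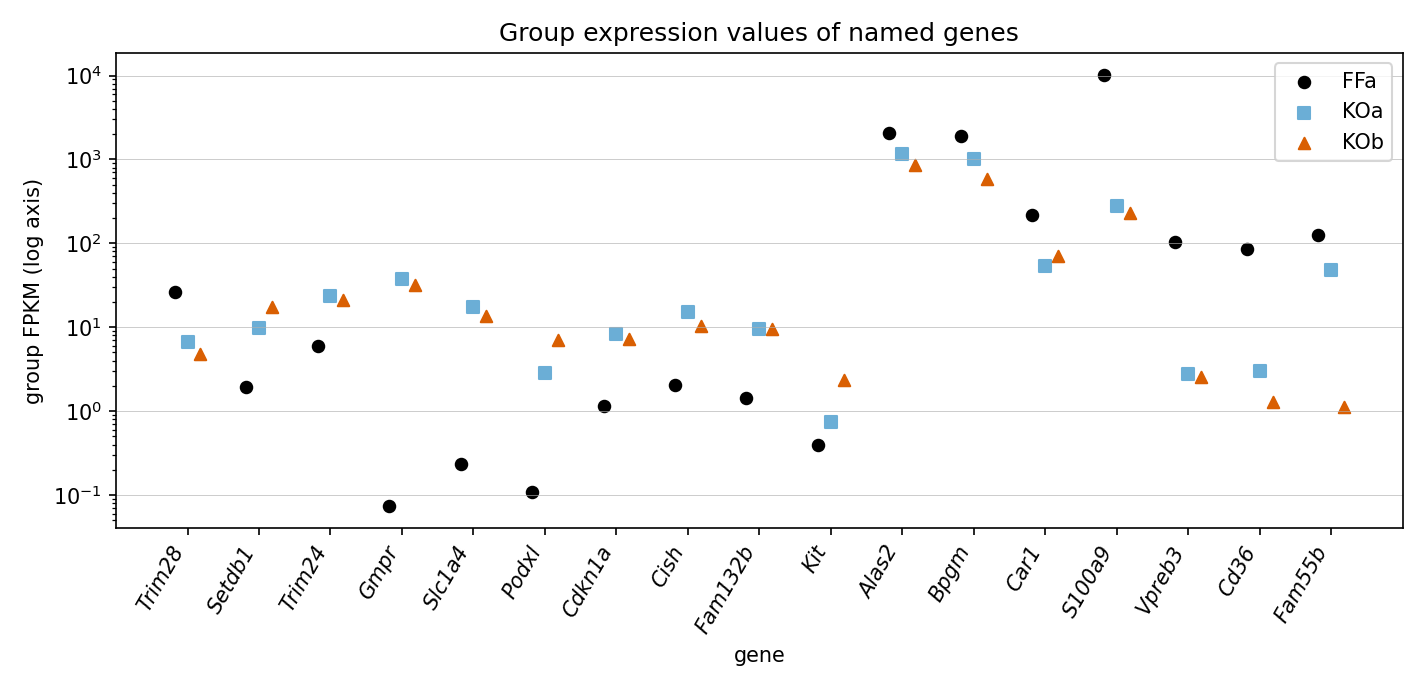
Group FPKM (log axis) of 17 genes in FFa (circles), KOa (squares) and KOb (triangles), 1 pooled value per group without an error bar. Trim28 lies at 26.0, 6.64 and 4.76, and S100a9 at 10284, 278 and 231.

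KOa against FFa compares mutant and control cells sorted through the same gate. In KOa, 860 genes were higher and 1516 lower of 10761 tested. The largest rises were in genes almost silent in the control. Gmpr, which encodes a guanosine monophosphate reductase of purine metabolism, rose from an FPKM of 0.0731 to 37.4 (log2 ratio 9.0 ± 1.33), and Fam159b rose from 0.126 to 66.7 (9.05 ± 1.14). Such folds start from a value near 0 and are loosely determined. Nccrp1 rose by 7.09 ± 1.16, the neutral amino acid transporter gene Slc1a4 by 6.20 ± 0.63, the ectonucleotidase gene Entpd3 by 5.27 ± 1.14 and Bambi, which encodes a pseudoreceptor of TGF-beta signalling, by 5.02 ± 0.68. Podxl (4.69 ± 0.78), Abhd6 (4.33 ± 1.45) and the heat shock gene Hspa1a (4.21 ± 0.83) were among the largest rises as well. With the deposited statistic read as a standard normal, the counts of called genes were 271 higher and 533 lower.

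Among the largest falls, the predicted gene Gm12839 had a log2 ratio of -6.05 ± 0.72 and the fibronectin gene Fn1 went from 8.21 to 0.170 FPKM (-5.60 ± 0.54). The pre-B cell gene Vpreb3 fell by 5.24 ± 0.42 and S100a9, a calprotectin subunit abundant in neutrophils, fell by 5.21 ± 0.21, from 10284 to 278 FPKM. S100a8, the gene of the other calprotectin subunit, went from 34935 to 14822 FPKM (-1.24 ± 0.39) and was not called in KOa. Cd36, the gene of a scavenger receptor for fatty acids, fell by 4.85 ± 0.34. Myl4 (-4.76 ± 1.14), Spib (-4.75 ± 0.70), the manganese transporter gene Slc30a10 (-4.54 ± 0.81), Hist1h4a (-4.51 ± 0.70) and Gpc4 (-4.51 ± 1.02) fell as well. Markers of leukocytes were among these genes, and the marker lists are described with their counts further on.

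Of the TRIM28 complex list, which holds the deleted gene itself, 3 members rose and 2 fell of 18 tested in KOa. Without Trim28, 3 rose and 1 fell of 17 (median log2 ratio -0.10). Setdb1, the histone H3 lysine 9 methyltransferase that acts with TRIM28, rose by 2.34 ± 0.55 and Trim24, a paralog of Trim28, rose by 2.0 ± 0.30. The list as a whole did not stand apart from random lists (median log2 ratio -0.15, mean 0.08, adjusted permutation p = 0.393). Among targets of p53, 8 were higher, 1 lower and 14 not called of 23 tested, or 10 higher and 1 lower adjusted over the list alone. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 2.87 ± 0.50 and Ddit4, an inhibitor of mTORC1 signalling, rose by 1.83 ± 0.42, while the death receptor gene Fas fell by 1.81 ± 0.97. Their list median of 0.41 had an adjusted permutation p of 0.00792, and cameraPR of limma with a preset correlation of 0.05 gave an adjusted p of 0.0739 (range over alternatives 0.00244 to 0.0739).

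Genes of the integrated and ER stress response were higher in 9 and lower in 2 of 23 tested (10 and 2 adjusted over the list alone). Trib3 (3.06 ± 1.04) and Chac1 (2.71 ± 0.56), both targets of the ATF4 and CHOP pathway, rose, and the asparagine synthetase gene Asns fell by 1.26 ± 0.30. The list median of 0.22 had an adjusted permutation p of 0.0368. That call was lost with an FPKM minimum of 5 (adjusted permutation p = 0.119) and with cameraPR at a correlation of 0.05 (adjusted p = 0.0913, limma; range over alternatives 0.00514 to 0.119). In the EPO and STAT5 response list 5 genes rose and 2 fell of 19 tested, with the STAT5 feedback inhibitor gene Cish at 2.90 ± 0.36. Its median of 0.09 did not pass (adjusted permutation p = 0.291), but cameraPR, which uses the mean, passed with an adjusted p of 0.00166 at 0.01 and 0.0173 at 0.05 (range over alternatives 0.00166 to 0.731).

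Among erythroid genes, late maturation genes were lower in 8 and higher in 1 of 25 tested in KOa. The carbonic anhydrase gene Car1 fell by 2.03 ± 0.30, from 220.5 to 53.9 FPKM, Acp5 fell by 0.99 ± 0.48 on the log2 scale and Ube2l6 fell by 0.97 ± 0.26. The list median of -0.27 did not pass (adjusted permutation p = 0.0577). With cameraPR at 0.01 and 0.05 the adjusted p values were 0.345 and 0.567 (limma, range over alternatives 0.0567 to 0.567). Of 13 heme synthesis genes, 1 rose and 3 fell: Cpox rose by 1.06 ± 0.32, and Alas2, the erythroid gene of the first enzyme of the pathway, fell by 0.84 ± 0.40 (list median -0.25, adjusted permutation p = 0.255). Of 14 iron genes, 2 rose, Fam132b, which encodes the iron hormone erythroferrone, rose by 2.76 ± 0.37 and Tfr2 rose by 0.71 ± 0.30. The iron list had a median of 0.07 and an adjusted permutation p of 0.469.

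Red cell membrane genes were higher in 1 and lower in 3 of 23 tested. The glucose transporter gene Slc2a1 rose by 2.06 ± 0.65, and the beta-spectrin gene Spnb1 fell by 1.49 ± 0.31 (list median 0.04, mean -0.01, adjusted permutation p = 0.393). Of 25 erythroid transcription factor genes 3 rose and 1 fell, with Bach1 rising by 0.86 ± 0.33 and Tfdp2 falling by 0.85 ± 0.31 (list median 0.05, adjusted permutation p = 0.467). Adult globin genes did not pass in any of the 3 tested (adjusted permutation p = 0.291). Beta-s was listed at 565663 FPKM in FFa and 715226 in KOa, and near-identical globin genes share reads, so the split between them is uncertain. Of 5 embryonic globin list genes, 1 fell, Hbq1a, fell by 1.38 ± 0.26 (list adjusted permutation p = 0.619). For the lists of these 2 paragraphs the counts adjusted over the list alone were the same. Where a list named with its counts has no such second count beside it or at the end of its paragraph, the counts were equal.

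In KOa, B cell markers fell in 19 of 24 tested and rose in 0, with a list median of -2.59 and an adjusted permutation p of 0.000593, the smallest that 10000 random lists can give after adjustment. Fcrla fell by 4.29 ± 0.62 and Cd79a, a chain of the B cell receptor complex, fell by 4.1 ± 0.55. Granulocyte markers fell in 12 and rose in 2 of 22 (median -0.68, adjusted permutation p = 0.000593; with cameraPR at 0.05, adjusted p = 0.0660, limma; range over alternatives 0.000593 to 0.0660). Ngp fell by 3.16 ± 0.26 and the lysozyme gene Lyz2 fell by 2.52 ± 0.25. Macrophage and monocyte markers fell in 11 of 22 (median -1.01, the same adjusted p), with the chemokine receptor gene Ccr2 at -3.08 ± 0.75. Dendritic cell markers fell in 4 of 9 (median -1.50, adjusted permutation p = 0.00866), and Irf8 fell by 2.89 ± 0.42.

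Megakaryocyte markers went the other way, with 4 higher and 2 lower of 12 tested in KOa. The platelet factor gene Pf4 rose by 2.57 ± 0.36, the platelet glycoprotein gene Gp1ba by 2.30 ± 0.41 and the integrin gene Itga2b by 1.85 ± 0.40. The median over 6 expressed members was 1.09 (adjusted permutation p = 0.00147), and with no expression minimum the median over all 12 tested was 0.18 and the adjusted permutation p was 0.265 (range over alternatives 0.00147 to 0.265). T and NK cell markers fell in 4 and rose in 1 of 16 (median -0.55, adjusted permutation p = 0.0531), and Cd2 fell by 2.72 ± 0.61. Mast cell, basophil and eosinophil markers rose in 3 and fell in 4 of 10 (adjusted permutation p = 0.173), with Prss34 at -2.82 ± 0.43. These 2 lists passed with an FPKM minimum of 5, but on only 3 members of the T and NK list and 4 of the mast cell list. The adjusted permutation p values were then 0.0205 (range over alternatives 0.0203 to 0.0773) and 0.00984 (range over alternatives 0.00984 to 0.173). Of 2 stromal and endothelial markers tested, Pecam1 fell by 1.00 ± 0.48, and the list got no test. Stem and early progenitor genes rose in 3 and fell in 7 of 17, and Lmo4 fell by 1.76 ± 0.46 (median over 10 expressed members -0.67, adjusted permutation p = 0.00990; with no expression minimum a median of -0.08 over all 17 and 0.940; cameraPR at 0.01, adjusted p = 0.309, limma; range over alternatives 0.00577 to 0.940). With q values adjusted over the list alone, 5 stem and early progenitor genes rose, granulocyte markers fell in 13, macrophage markers in 12 and dendritic markers in 5, with the other counts of these lists unaltered.

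Histone genes fell in 31 and rose in 5 of 60 tested in KOa, with a median of -0.71 and an adjusted permutation p of 0.000593. Hist1h2ae fell by 2.81 ± 0.23 and Hist1h4k fell by 2.80 ± 0.18, but near-identical histone genes share reads and single members are uncertain. Ribosomal protein genes fell in 21 and rose in 6 of 92. The symbol rule of this list also takes in Rps6k kinase genes. Without these and Rpl39l, 19 fell and 5 rose of 83. Rps14 fell by 1.44 ± 0.21 and Rpl15 fell by 1.34 ± 0.28 (list median -0.22, adjusted permutation p = 0.0158). With cameraPR the ribosomal list was lost, at adjusted p values of 0.401 and 0.680 (limma; range over alternatives 0.0107 to 0.680). Proteasome genes rose in 8 and fell in 4 of 37 (adjusted permutation p = 0.162), among them Psmc2 at 0.84 ± 0.27 and the immunoproteasome gene Psmb8 at -1.65 ± 0.43. Mitotic genes rose in 2 and fell in 5 of 30, and Aurkb fell by 0.65 ± 0.27 (adjusted permutation p = 0.0577), and DNA replication genes fell in 2 of 30, and Mcm2 fell by 0.50 ± 0.28 (adjusted permutation p = 0.0911). Adjusted over the list alone, 9 proteasome genes rose and 1 DNA replication gene fell, with the other counts of these lists unaltered.

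Interferon response genes fell in 7 and rose in 1 of 36 tested, with Ifi27l2a falling by 3.55 ± 0.48 and Ifih1, an RNA sensor gene, falling by 1.45 ± 0.33. The list median of -0.23 did not pass (adjusted permutation p = 0.145; with no expression minimum 0.0499, range over alternatives 0.0499 to 0.600). Autophagy genes rose in 4 and fell in 3 of 38, with the lysosomal regulator gene Tfeb falling by 2.44 ± 0.94 and the mitophagy receptor gene Optn rising by 1.09 ± 0.27 (adjusted permutation p = 0.409). Zfp-named zinc finger genes rose in 12 and fell in 11 of 199, Zfp954 rising by 2.46 ± 0.89 (adjusted permutation p = 0.257; with no expression minimum 0.0461, range over alternatives 0.0461 to 0.750). Imprinted genes rose in 1 and fell in 1 of 14, Zrsr1 rising by 0.73 ± 0.34 and Axl falling by 0.72 ± 0.34 (adjusted permutation p = 0.801). Axl is also in the macrophage and monocyte marker list. Of 3 germline genes tested, Syce2 rose by 0.64 ± 0.25 and Ddx4 fell by 2.56 ± 1.02, with too few expressed for a list test. For these lists, adjusted over the list alone, 8 interferon genes fell, and 10 zinc finger genes rose and 9 fell.

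KOb against FFa sets the cells with the stronger deletion, sorted as TER119-negative, against the control. In KOb, 1352 genes were higher and 1614 lower of 10584 tested. Gmpr (8.78 ± 1.33), Fam159b (7.87 ± 1.14), Nccrp1 (6.21 ± 1.16), Podxl (6.01 ± 0.77) and Slc1a4 (5.86 ± 0.63) had the largest log2 rises. They were followed by Bambi (4.99 ± 0.67), Entpd3 (4.76 ± 1.14), D330045A20Rik (4.30 ± 0.97), Abhd6 (4.29 ± 1.45) and 1700097N02Rik (4.2 ± 0.48). The largest falls were in Gm12839 (-7.60 ± 1.04), Fn1 (-7.19 ± 0.86) and Fam55b, which went from 124 to 1.12 FPKM (-6.80 ± 0.38). They were followed by falls of Slc30a10 (-6.09 ± 1.27), Cd36 (-6.08 ± 0.40), the reelin gene Reln (-5.92 ± 0.77), Akap7 (-5.64 ± 0.93), S100a9 (-5.48 ± 0.21), Vpreb3 (-5.35 ± 0.43) and the tachykinin gene Tac2 (-5.33 ± 0.71). S100a8 fell by less than S100a9, with a log2 ratio of -1.53 ± 0.38 in KOb. With the statistic read as a standard normal, 383 genes were higher and 627 lower.

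Late maturation genes fell in 20 and rose in 1 of 25 tested in KOb, with a list median of -0.73 (adjusted permutation p = 0.00111). Bpgm, which makes the 2,3-bisphosphoglycerate of red cells, fell by 1.73 ± 0.35, from 1926 to 581 FPKM, Car1 fell by 1.63 ± 0.30 and Fam46c fell by 1.52 ± 0.29. Red cell membrane genes fell in 13 and rose in 1 of 23 (median -0.62, adjusted permutation p = 0.00930), with Spnb1 falling by 2.08 ± 0.31 and Epb4.1, the gene of protein 4.1, falling by 1.16 ± 0.37. The membrane call was lost with cameraPR, at adjusted p values of 0.0778 and 0.238 (limma; range over alternatives 0.00930 to 0.238). Heme synthesis genes fell in 7 and rose in 0 of 13 (adjusted permutation p = 0.231), with Alas2 falling by 1.27 ± 0.39, the mitochondrial iron importer gene Slc25a37 falling by 1.18 ± 0.37 and Fech falling by 0.86 ± 0.34. The gate differs from that of the control here, and TER119 is itself a mark of maturation.

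Iron genes rose in 4 and fell in 3 of 14 in KOb (adjusted permutation p = 0.184), with Fam132b rising by 2.74 ± 0.37 and the heme oxygenase gene Hmox1 falling by 0.86 ± 0.28. Hmox1 is also in the macrophage and monocyte marker list. Erythroid transcription factor genes rose in 1 and fell in 4 of 25 (adjusted permutation p = 0.331), with Bcl11a rising by 1.18 ± 0.42 and Foxo3 falling by 0.82 ± 0.28. Adult globin genes passed in 0 of 3, at 247300 FPKM for Beta-s (list adjusted permutation p = 0.409), and embryonic globin list genes fell in 2 of 5, with Hbq1b at -0.84 ± 0.22 (list adjusted permutation p = 0.409). Stem and early progenitor genes rose in 7 and fell in 5 of 18 (median 0.13, mean -0.06, adjusted permutation p = 0.738), with the stem cell factor receptor gene Kit at 2.57 ± 0.50, Cd34 at 2.74 ± 1.23 and Meis1 at 2.45 ± 1.06. Adjusted over the list alone, 21 late maturation, 14 membrane, 8 heme and 5 erythroid transcription factor genes fell, and 1 heme gene and 2 transcription factor genes rose.

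Targets of p53 rose in 10 and fell in 1 of 24 tested in KOb (median 0.53, adjusted permutation p = 0.00632; with an FPKM minimum of 5, adjusted permutation p = 0.0546, range over alternatives 0.00261 to 0.0546). Perp rose by 4.01 ± 1.34, Cdkn1a by 2.65 ± 0.50 and the cyclin gene Ccng1 by 1.88 ± 0.31. Integrated and ER stress genes rose in 7 and fell in 2 of 22 (median 0.29, adjusted permutation p = 0.0342), and Psat1, a serine synthesis gene, rose by 1.68 ± 0.34. The stress call was lost with cameraPR at 0.01 (adjusted p = 0.0508, limma) and with an FPKM minimum of 5 (adjusted permutation p = 0.155; range over alternatives 0.0342 to 0.185). EPO and STAT5 response genes rose in 7 and fell in 4 of 19, with the adaptor gene Gab1 falling by 2.79 ± 0.47 (adjusted permutation p = 0.366; cameraPR at 0.01 passed with an adjusted p of 0.00456, range over alternatives 0.00456 to 0.877). Setdb1 rose by 3.16 ± 0.55 and Trim24 by 1.83 ± 0.30 in the TRIM28 list, of which 3 rose and 2 fell of 18 (adjusted permutation p = 0.971). Without Trim28, 3 genes of that list rose and 1 fell of 17 (median log2 ratio 0.12). With q values adjusted over the list alone, 11 p53 targets rose and 2 fell, 8 stress genes rose and 3 TRIM28 list genes fell.

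Histone genes fell in 47 and rose in 0 of 60 tested in KOb (median -1.18, adjusted permutation p = 0.000593), with Hist1h4j falling by 3.03 ± 0.48 and Hist3h2ba falling by 1.91 ± 0.20. Ribosomal protein genes rose in 10 and fell in 4 of 91, with a median of 0.09 against -0.23 for random lists of like expression (adjusted permutation p = 0.000593). Without the Rps6k kinase genes and Rpl39l, 8 rose and 4 fell of 83. The ribosomal call was lost with cameraPR, at adjusted p values of 0.383 and 0.672 (limma; range over alternatives 0.000593 to 0.672). Rpl5 rose by 0.73 ± 0.28 and Rpl39 fell by 0.74 ± 0.28. Proteasome genes rose in 14 and fell in 1 of 37 (median 0.38, adjusted permutation p = 0.00147; cameraPR at 0.01, adjusted p = 0.115, limma, range over alternatives 0.000593 to 0.342), and Psmd7 rose by 0.86 ± 0.28. Mitotic genes fell in 10 of 30 (median -0.39, adjusted permutation p = 0.0117; cameraPR at 0.01, adjusted p = 0.190, limma, range over alternatives 0.00958 to 0.406), and Nusap1 fell by 0.71 ± 0.31. DNA replication genes fell in 2 of 30, and Tk1 fell by 0.75 ± 0.30 (adjusted permutation p = 0.393). Adjusted over the list alone, 48 histone and 14 mitotic genes fell, and 9 ribosomal protein and 15 proteasome genes rose.

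Interferon response genes fell in 10 and rose in 1 of 36 tested in KOb (median -0.44, adjusted permutation p = 0.00262; cameraPR at 0.01, adjusted p = 0.0584, limma, range over alternatives 0.00163 to 0.238), with Ifi27l2a falling by 3.66 ± 0.49 and Ifitm3 falling by 1.48 ± 0.21. Autophagy genes fell in 8 and rose in 2 of 38 (adjusted permutation p = 0.0470), with the mitophagy receptor gene Bnip3l falling by 0.88 ± 0.30. That call was lost with an FPKM minimum of 5 (adjusted permutation p = 0.100) and with cameraPR at 0.01 (adjusted p = 0.383, limma; range over alternatives 0.0470 to 0.612). Zfp-named genes rose in 22 and fell in 12 of 201 (adjusted permutation p = 0.903; with no expression minimum a median of 0.12 and 0.0420, range over alternatives 0.0420 to 0.903), and Zfp324 rose by 2.07 ± 0.69. Imprinted genes rose in 2 and fell in 1 of 13 (median 0.18, mean -0.03, adjusted permutation p = 0.517), and the growth regulator gene Grb10 rose by 2.45 ± 0.89. Of 4 germline genes tested, Syce2 rose by 0.72 ± 0.25 and Ddx4 fell by 1.81 ± 0.85. For these lists, adjusted over the list alone, 11 interferon genes fell, and 20 zinc finger genes rose and 11 fell.

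Leukocyte markers were low in KOb as well. B cell markers fell in 21 of 24 tested (median -2.43), macrophage and monocyte markers in 19 of 21 (-1.48), and T and NK cell markers in 8 of 15, with 1 higher (-1.11). Granulocyte markers fell in 14 and rose in 3 of 22 (-0.76), and the adjusted permutation p was 0.000593 for each of these 4 lists. Pax5, a B cell transcription factor gene, fell by 4.1 ± 1.16, Ctss fell by 2.21 ± 0.32, Il7r fell by 2.87 ± 0.66 and Ngp fell by 3.36 ± 0.26, while the neutrophil cathepsin gene Ctsg rose by 2.59 ± 0.36. Dendritic cell markers fell in 5 of 10, and Siglech fell by 4.64 ± 1.27 (adjusted permutation p = 0.0155). Megakaryocyte markers rose in 5 and fell in 2 of 12, and Gp5 rose by 3.39 ± 0.84 (median over 7 expressed members 2.13, adjusted permutation p = 0.000593; with no expression minimum a median of 0.34 over all 12 and 0.255, range over alternatives 0.000581 to 0.255). Mast cell, basophil and eosinophil markers rose in 2 and fell in 4 of 11, and Ear2 fell by 2.41 ± 0.74 (adjusted permutation p = 0.0755; cameraPR at 0.01 passed with an adjusted p of 0.0140, range over alternatives 0.0140 to 0.665), and of 2 stromal markers Pecam1 fell by 0.72 ± 0.46. Adjusted over the list alone, 20 macrophage, 10 T and NK and 3 megakaryocyte markers fell, and 3 markers of the mast cell list rose.

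**Figure D2:**
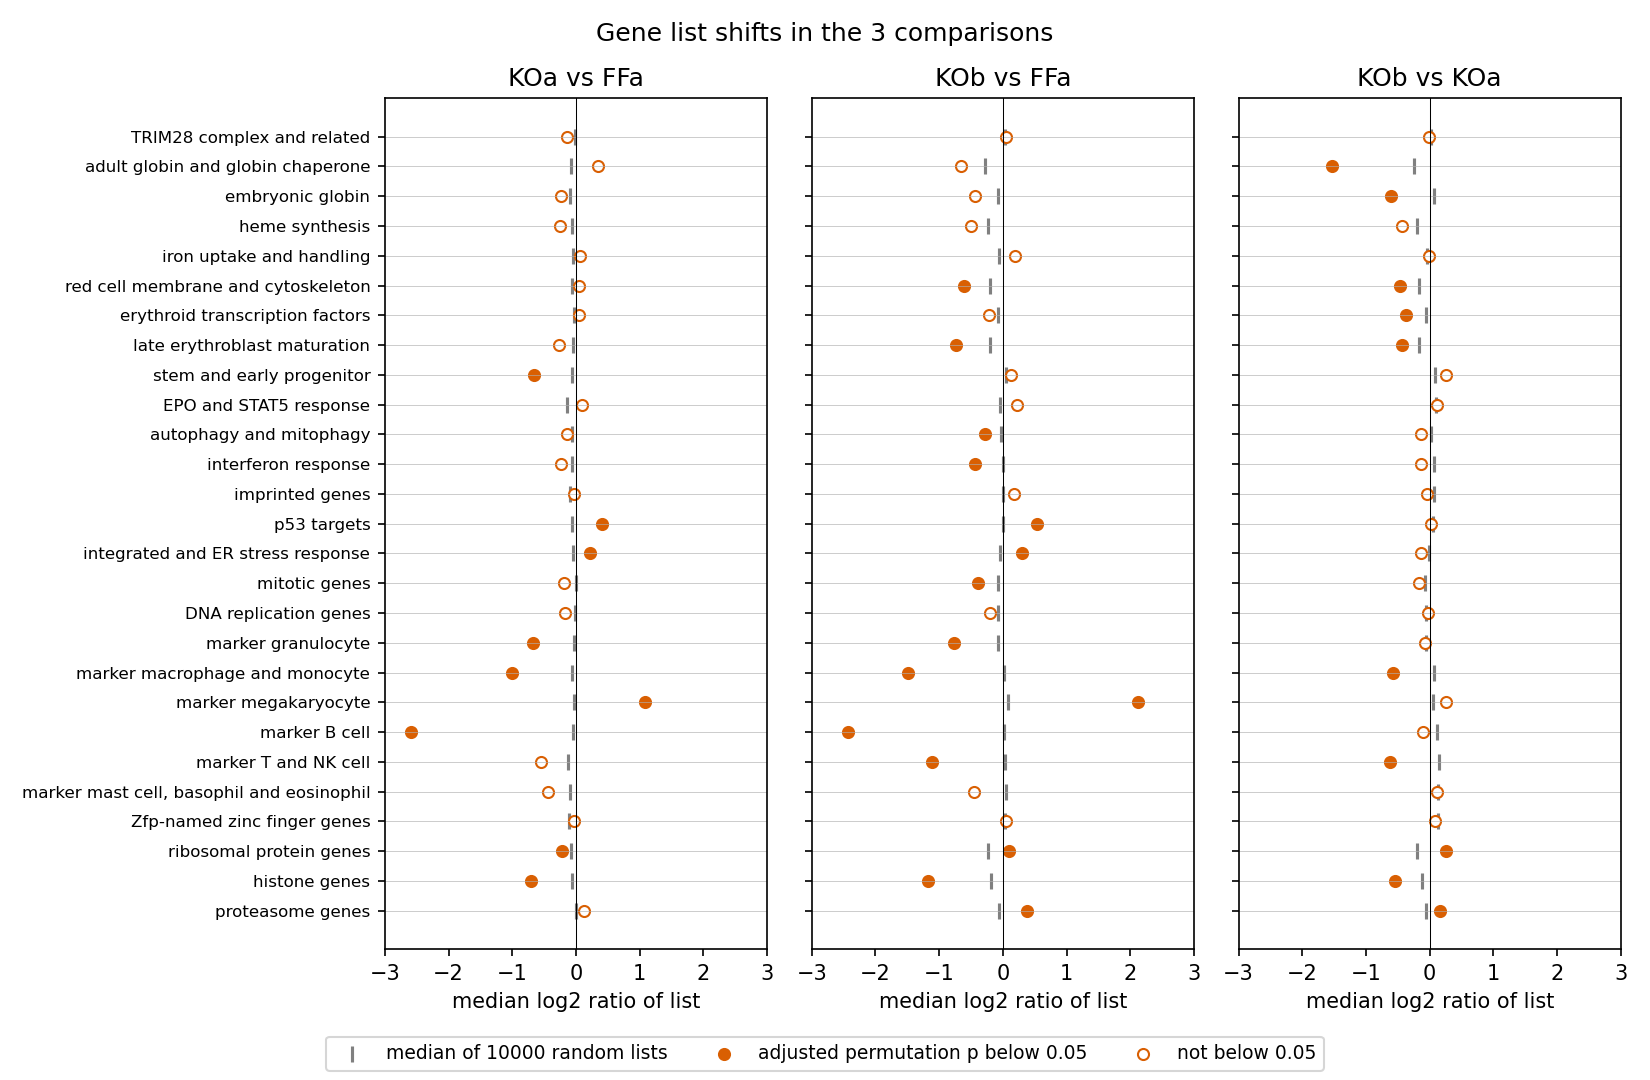
Median log2 ratio (circles) of the gene lists tested in all 3 comparisons, with the median of 10000 random lists of like expression as a grey tick. Filled circles have an adjusted permutation p below 0.05, and the B cell markers lie at -2.59 and -2.43 in the mutants against the control.

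KOb against KOa compares the mutant populations, which differ in both the degree of deletion and the gate. In KOb, 1052 genes were higher and 648 lower of 10468 tested, or 199 and 83 with the statistic read as a standard normal, under which 46 of the named gene results of this comparison lost their call. The share of higher calls, 61.9%, was 51.4% with an FPKM minimum of 5 and 75.4% with a 2-fold minimum. The glutathione transferase gene Gstp1 rose from 4.66 to 35.3 FPKM (2.92 ± 0.36), Hemt1 rose by 3.69 ± 1.02, the chromatin protein gene Hmga1 rose by 2.91 ± 1.36 and the deoxycytidylate deaminase gene Dctd rose by 2.86 ± 0.81. Atp6v0c (2.74 ± 0.55), Fam195a (2.72 ± 0.69), Adi1 (2.54 ± 0.55), Gm9320 (2.47 ± 0.63), 1810013D10Rik (2.34 ± 0.78) and Gml (2.33 ± 0.81), listed at 0 in FFa, rose too. Fam55b fell by 5.42 ± 0.38, from 47.8 to 1.12 FPKM, followed by Xkrx (-2.61 ± 0.43), Hist1h2br (-2.29 ± 0.56), Hist1h2af (-2.25 ± 0.19) and A130077B15Rik (-2.16 ± 0.55). Tac2 (-1.98 ± 0.77), Olfr856-ps1 (-1.96 ± 0.34), 4932411L15 (-1.93 ± 0.38), Zfp488 (-1.86 ± 0.39) and 4930470H14Rik (-1.84 ± 0.32) completed the falls.

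Erythroid maturation genes were lower in KOb than in KOa. Membrane genes fell in 12 and rose in 0 of 23 (median -0.47, adjusted permutation p = 0.0214), with Icam4 falling by 0.96 ± 0.24. Late maturation genes fell in 11 of 25 (median -0.43, adjusted permutation p = 0.0342), and the ubiquitin ligase gene Ube2o fell by 0.91 ± 0.31. Erythroid transcription factor genes fell in 7 and rose in 2 of 25, and Zfpm1, which encodes the GATA1 partner FOG1, fell by 0.78 ± 0.29 (median -0.37, adjusted permutation p = 0.00930; cameraPR at 0.05, adjusted p = 0.0739, limma, range over alternatives 0.00374 to 0.0739). Heme genes fell in 6 and rose in 1 of 13 (median -0.44, adjusted permutation p = 0.173; cameraPR at 0.01 passed with an adjusted p of 0.0287, range over alternatives 0.0287 to 0.181). The median of the 3 adult globin genes matched, of 7 symbols, was -1.53 (adjusted permutation p = 0.00374) although 0 passed singly. An entry that joins Hbb-b1 and Hbb-b2, which the list leaves out, was listed at 12883 FPKM in KOa and 72151 in KOb, the other way although not called, and near-identical globin genes share reads. Of the embryonic globin list, 2 of 5 genes fell (median -0.60, adjusted permutation p = 0.0272). With q values adjusted over the list alone, 13 membrane, 13 late maturation, 9 transcription factor and 1 adult globin gene fell, and 2 late maturation genes rose.

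Ribosomal protein genes were higher in KOb than in KOa in 27 and lower in 2 of 92 (median 0.26, adjusted permutation p = 0.000593; cameraPR at 0.05, adjusted p = 0.0607, limma, range over alternatives 0.000418 to 0.0607). Without the Rps6k kinase genes and Rpl39l, 26 were higher and 2 lower of 83. Rpl15 rose by 1.65 ± 0.29 and Rps14 by 1.40 ± 0.22. Proteasome genes rose in 9 and fell in 0 of 37, and Psmb5 rose by 1.57 ± 0.42 (adjusted permutation p = 0.0142; cameraPR at 0.01, adjusted p = 0.277, limma, range over alternatives 0.0134 to 0.554). Histone genes fell in 24 and rose in 6 of 59, and Hist1h3e fell by 1.81 ± 0.19 (median -0.55, adjusted permutation p = 0.000593). Macrophage markers fell in 7 of 21, and the complement gene C1qc fell by 1.23 ± 0.33 (median -0.58, adjusted permutation p = 0.000593), and T and NK cell markers in 1 of 14, with Tcf7 at -0.74 ± 0.44 (median -0.62, adjusted permutation p = 0.00262). Kit rose by 1.66 ± 0.42 and the progenitor transcription factor gene Myb by 1.25 ± 0.33, in a stem and early progenitor list with 4 higher and 2 lower of 17 (adjusted permutation p = 0.393; with an FPKM minimum of 5, 0.00719, range over alternatives 0.00719 to 0.467). B cell markers differed in 3 of 20, all lower, among them H2-Aa at -1.12 ± 0.37 (adjusted permutation p = 0.184; 0.0205 with an FPKM minimum of 5 and 0.0358 with none, range over alternatives 0.0205 to 0.362). For these lists, adjusted over the list alone, 30 ribosomal protein, 7 histone and 5 stem genes rose, 27 histone genes, 8 macrophage and 1 B cell marker fell, and 0 T and NK cell markers passed.

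KOa and KOb shared 499 genes called higher and 988 called lower against FFa, of 10427 genes tested in both. Independent lists of these sizes would share 103.7 and 234.7. Both comparisons use the same control libraries, and in 100 simulations of unchanged groups that share FFa, on 8497 expressed genes, 127.5 genes were called higher and 129 lower in both on average, against 465 and 848 observed. The log2 ratios of these genes had the same sign in 72.3%, against 66.5% in the simulations, and Pearson's r across genes, which are not independent replicates, was 0.797 against 0.576. Their covariance was 0.554 against 0.604 simulated, a difference of -0.05, so no shared effect could be estimated from the covariance. The other simulated values rest on the same implied spread, which gave more covariance than was observed, so they may not match these data. The control could not be split, so the overlap stands with the shared control libraries in it. Of the 499 genes higher in both, 69 also differed between KOb and KOa (39 higher and 30 lower in KOb). Of the 988 lower in both, 108 did, with 27 higher and 81 lower in KOb.

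**Figure D3:**
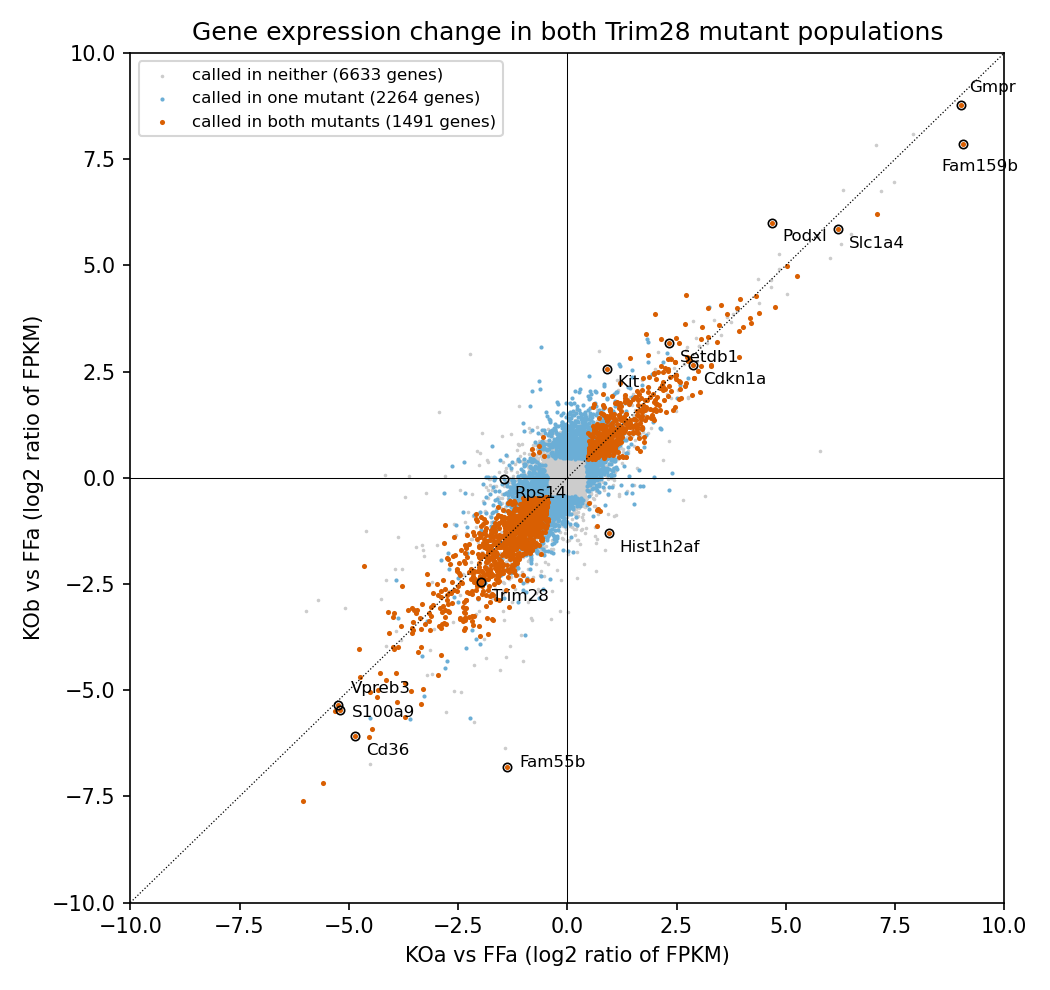
Log2 ratio of FPKM to FFa in KOa (horizontal axis) and KOb (vertical axis) for 10388 genes tested in both with a finite ratio, coloured by whether the gene was called in neither (6633), one (2264) or both (1491) mutants. Trim28 lies at -1.97 and -2.45, and the dotted line marks equal ratios.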

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

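The test restricted to the Olfr, Vmn1r and Krtap families was chosen only after the result was seen, and the other tests of this part were written before it.

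A set of 12 genes was called in opposite directions in KOa and KOb against the same control. The difference between the mutants was called for all 12 in the authors' deposited table. That call lends no separate support, since the log2 ratio between the mutants is the difference of their opposite ratios to FFa. At a q below 0.01 there were 5 such opposite calls, and 5 with the statistic read as a standard normal. Hist1h2af, Hist1h2ak, Hist1h2an, Hist1h3e, Abi3 and Ypel4 were higher in KOa and lower in KOb than in FFa, with Hist1h2af at 174 FPKM in FFa, 337 in KOa and 70.7 in KOb. Cd48, Ppan, Ppia, Rpl10a, Suclg1 and Tagln2 were lower in KOa and higher in KOb, with Ppia at 65.7, 44.4 and 129 FPKM. Histone genes made up 4 of the 12, and their near-identical copies share reads.

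Genes of 5 families with tissue-restricted expression, almost all too low to enter the comparisons, had higher values in KOa than in the control. Among the genes not tested, the mean FPKM in KOa was 2.69 times that in FFa for the olfactory receptor genes (Olfr), 3.34 times for the vomeronasal receptor genes Vmn1r, 3 times for Vmn2r, 2.62 times for the keratin-associated genes (Krtap) and 4.23 times for the beta-defensin genes (Defb). Over all genes of each family the ratios were 2.60, 3.38, 3.60, 2.54 and 4.23. The levels were low, with a mean over the Olfr genes not tested of 0.0266 FPKM in FFa, 0.0715 in KOa and 0.0200 in KOb.

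Deeper sequencing of KOa leaves a mean FPKM unaltered, and the lowest of the 5 ratios was 2.54, above the bound set for that explanation. Loss of TRIM28 repression would give an excess in KOb too, and the largest KOb excess was 0.345 of the KOa excess, so it stays open for the families as a set. The upper bound on that share over genes was -0.09 for Olfr, 0.05 for Vmn1r and 0.253 for Krtap, but these genes lie near 0 FPKM, no spread between libraries is known and the families were picked because their KOb means lay near those of FFa, so it stays open for all 3. Reads from outside mature transcripts in the KOa libraries stay open too: 5 of 5 families had their highest mean in KOa, which restates the pattern, and no value here separates such reads. Without values per library, whether 1 library carried the signal could not be seen.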

How the results depend on the processing

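Calls with the deposited statistic read as a standard normal, calls without genes listed at 0 or without marker genes, and 2 trimmed lists were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the labels do not pair the libraries and only group values were used. For the same reason leaving out each replicate, a replicate block and other splits of the samples were not run. The depth per library is unknown, so what depth limits could not be computed.

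The counts of higher and lower genes are given in this order. A lower q, an FPKM minimum and a 2-fold minimum give fewer genes by construction, while the normal statistic is another p, and 782, 990 and 267 of its calls in the 3 comparisons were also calls with the deposited p. In KOa against FFa they were 547 and 975 at a q below 0.01, 501 and 682 with an FPKM of at least 5, 364 and 786 with a 2-fold change, 153 and 339 with a 2-fold change of FPKM + 1, and 271 and 533 with the statistic read as a standard normal. In KOb against FFa they were 825 and 1104, 718 and 854, 591 and 866, 244 and 404, and 383 and 627. In KOb against KOa they were 557 and 326, 527 and 498, 346 and 113, 116 and 37, and 199 and 83. Shared calls numbered 314 higher and 665 lower at a q below 0.01, and 170 higher and 400 lower with the normal statistic. Without marker genes the counts were 850 and 1459, 1341 and 1540, and 1050 and 635. Only genes of the marker lists are taken out in this setting, so it cannot show how many other calls come from carried-over cells. The share of higher calls moved by more than 10 points only in KOb against KOa, from 61.9% to 51.4% with an FPKM of at least 5, and to 75.4% and 75.8% with the 2-fold settings; the cause was not tested.

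The log2 ratio of Trim28 was -1.92 and -1.82 in KOa and -2.46 and -2.23 in KOb relative to the median ratio and with FPKM + 1. Of 290 results for named genes, 56 lost their call at a q below 0.01, 102 with the normal statistic and 4 with adjustment within the comparison. Centring and FPKM + 1 leave the deposited q and thus these calls as they are by construction. Of 83 list results, cameraPR ended 10 calls and added 7 at a correlation of 0.01, and ended 15 and added 3 at 0.05. Lists called went from 10 to 11 and 6 at these correlations in KOa against FFa, from 16 to 11 and 11 in KOb against FFa, and from 10 to 11 and 7 in KOb against KOa. Besides the correlation, cameraPR tests means instead of medians and does not match genes on expression, as the random lists do. Which of these differences moved the calls was not tested. An FPKM of at least 5 ended 4 calls and added 5 of 77, no minimum ended 4 and added 6, FPKM + 1 ended 1, and trimming the 2 lists altered 0. Subtracting the median moves a list and its random lists alike, so its permutation p could not change.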

Other observations

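The gene groups of the first 2 paragraphs, and the tests on B cell markers, granulocyte markers and the TER119 gate, were chosen only after the result was seen. The test of neighbouring genes was written before.

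Ribosome biogenesis genes, which build ribosomes in the nucleolus, were higher in KOb than in FFa in 22 of 26 tested and higher in KOb than in KOa in 24, while in KOa against FFa 0 were higher and 1 was lower. The nucleolar gene Npm1 rose by 1.27 ± 0.30 in KOb against FFa and the RNA polymerase I subunit gene Polr1b by 1.79 ± 0.49. These counts include Srm, a spermidine synthase gene and not a ribosome assembly gene, which rose by 2.04 ± 0.29 in KOb against FFa. Heat shock genes were higher in 5 of 11 tested in KOa and in 9 in KOb, with 0 lower in either. Hspa1b rose by 3.88 ± 0.80 in KOa and 3.99 ± 0.79 in KOb, and the mitochondrial chaperonin gene Hspd1 rose by 1.73 ± 0.33 in KOb, with a ratio of 0.09 ± 0.36 in KOa. No list test was run on these groups.

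Of 6 genes of neutrophil azurophil granules and their precursors, 4 were higher in both mutants, among them the myeloperoxidase gene Mpo (1.41 ± 0.29 in KOa and 1.75 ± 0.29 in KOb) and Ctsg (2.24 ± 0.36 and 2.59 ± 0.36). Elane and Prtn3 share a locus entry, and their standard errors of 5.75 and 9.05 in KOa leave them undetermined. Of 10 genes of later granules and neutrophil cytosol, 7 were lower in KOa and 9 in KOb, among them Camp (-2.01 ± 0.21 and -2.40 ± 0.21), with 0 higher. The difference between these groups was not tested. Stefin A genes, neighbours on chromosome 16, were higher in 5 of 5 in KOa and 4 in KOb, Stfa3 by 3.30 ± 0.36 and 2.64 ± 0.36.

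B cell transcripts were lower in both mutants, although cells had been sorted by CD71 and TER119. Of 22 expressed B cell markers, 95.5% had a negative log2 ratio in KOa and 90.9% in KOb, and the abundant marker Vpreb3 went from 104 FPKM in FFa to 2.74 in KOa and 2.54 in KOb. Fewer B-lineage cells carried in the mutant sorts stay open as an explanation, since these percentages restate the pattern and lend it no support. One smaller share of granulocytes of all stages alike would lower all granulocyte markers. However, 2 of them, Ctsg and Mpo, were called higher in both mutants, while Ngp fell. The bound for this test was set after these calls were seen. A smaller share of some granulocyte stages only was not tested and stays open. Another list holds 0 of the 24 B cell and 22 granulocyte markers, how far erythroblasts express them is not known, and no biological explanation was tested.

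Late maturation genes were called lower in 20 of 25 and red cell membrane genes in 13 of 23 in KOb, whose gate differs from that of FFa. The membrane list call was lost with cameraPR (adjusted p values of 0.0778 and 0.238, limma). The TER119 gate alone gives no fall in KOa, sorted like the control, yet 8 of 25 late maturation genes were called lower in KOa and 1 higher, and 3 of 23 membrane genes lower and 1 higher, with Car1 at -2.03 ± 0.30 and Spnb1 at -1.49 ± 0.31, and the gate does not explain these falls. These 8 and 3 genes were lower in KOb too, but random lists of like expression had a median of 5 and 4 genes called lower in KOa, with adjusted permutation p values of 0.163 and 0.853 for the numbers of the 2 lists (0.580 and 0.942 with the statistic read as a standard normal). For the lists as a whole gate and deletion cannot be told apart, since KOb differs from FFa in both and a p that misses the threshold does not show that the genes did not differ. Whether the effect differs with the degree of deletion was not tested, since no group had the stronger deletion in the TER119-positive gate.

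Genes called in both mutants lay beside each other on the chromosomes more often than in shuffles of the calls. Of 10358 tested genes in order, 59 neighbouring pairs were both called higher, against a median of 24 and a 95th percentile of 32 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). For lower calls there were 152 pairs against a median of 93 (permutation p = 0.0001). Without pairs that share a symbol stem or overlap, 52 higher pairs stood against 21 and 115 lower pairs against 83 (permutation p = 0.0001 and 0.0003). Runs of neighbours called lower in both mutants included histone genes and the B cell markers H2-Ab1, H2-Aa and H2-Eb1. Related genes with unlike symbols were not taken out by the stem rule. Local clusters of genes that change together stay open as an explanation, but the pair counts restate that pattern and lend it no support. Neighbours of like expression were not matched in the shuffles.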
